A study of Mus musculus with 6 samples.

How the data were processed

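Cells labelled long-term haematopoietic stem cells (LT-HSCs) from the bone marrow of mice of an Mmrn1-GFP genotype were profiled by RNA-seq. GFP stands for green fluorescent protein. Per the labels, 3 libraries came from cells called Mmrn1-low and 3 from cells called Mmrn1-high. Mmrn1 encodes multimerin 1, a platelet and endothelial protein. The labels do not say whether the replicates came from separate mice or sorts, and the surface gate is not given in the sources used here. Per the labels' protocols, poly-A RNA was selected from total RNA, stranded paired-end libraries were made and an Illumina NovaSeq sequencer was used.

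The deposited table held raw read counts and FPKM values for 55487 Ensembl mouse genes in each library. The submitters' processing notes name CASAVA 1.8, HISAT2, StringTie and edgeR and the genome build GRCm38, without the role or order of each tool. The strand setting of the counting and any filter are not given in the sources used here. Per the file headers, the counts are per gene and were not normalised. The authors' FPKM values equalled the count divided by gene length and by the library's total count, to a relative deviation of at most 3.11e-05 among genes with at least 200 counts, so they carried no correction for composition. Gene models of GENCODE release M21 were used for biotypes and for exon overlap, and 55141 of the gene identifiers matched, 99.4% of them with identical coordinates. Of the genes in the table, 28316 had no count in any library.

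Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust fitting, TMM factors (which correct library size for composition), the filterByExpr rule for low counts and the group as the only term. This left 15419 genes. The log2 fold change is Mmrn1-high minus Mmrn1-low, its standard error (SE) is the fold change divided by the square root of F, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM (counts scaled to a common library total), given as mean ± SD of 3 libraries. The common dispersion, a single value over all genes, was 0.0126, a coefficient of variation of 11.2% between libraries of a group. For pairs of libraries of a group, the chi-square per gene against counting noise had a median of 0.829 to 1.28. Its mean was 7.08 to 11.7, so the spread was uneven between genes and the common value does not describe a typical gene. Gene lists were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, two-sided, and adjusted over the 34 lists. The lists, the test, the rule for named genes and the alternatives were fixed before the data were examined. They covered stem cell, lineage, cell cycle, metabolic, stress and signalling genes and markers of other marrow cell types, written from general knowledge, and lists share members.

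Named genes were Mmrn1 and 8 surface genes used to sort stem cells (Kit, Ly6a, Slamf1, Cd48, Cd34, Flt3, Procr and Itga2b), then the 10 largest fold changes in each direction among called genes at or above the median expression with groups that did not overlap, leaving out predicted and clone-based models. To these were added up to 4 members with the smallest p of each called list or list of another cell type, up to 2 of each other list, and any gene in a count of 5 or fewer. Some genes that this rule takes are not reported here. Of the 133 genes so named, 33 share exon bases with another annotated gene, and without a stated strand setting such reads cannot be assigned.

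The count totals were 16657398, 14288095 and 30180151 for Mmrn1-low replicates 1 to 3 and 11595104, 30909990 and 14236755 for Mmrn1-high replicates 1 to 3. A count of 3 corresponds to between 0.0971 and 0.259 CPM in these libraries. The procedure was tested on counts simulated for 15211 genes from these libraries' means and totals, with 200 changed genes. In that simulation of the same comparison, 6 of 50 genes changed by 1.25-fold, 24 of 50 changed by 1.5-fold, 42 of 50 changed by 2-fold and 47 of 50 changed by 4-fold were recovered, and 4 of 123 calls were false. Of 100 random lists, 0 passed 0.05, but their genes were simulated independently, so this cannot test the preset correlation.

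The alternatives were relative log expression factors, library size alone, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, protein-coding genes alone, limma-trend on the authors' FPKM as log2(FPKM + 1) with at least 1 FPKM in 3 libraries, a pseudocount of 0.1, no FPKM filter, leaving out each library, an adjusted p under 0.01, an absolute log2 fold change of at least 1, an estimated correlation in camera, and the rotation test fry. Another 6 lists were written, and FPKM divided by the TMM factors added, after values had been seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1.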

Results

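The data were 6 RNA-seq libraries of mouse cells labelled LT-HSCs, the cells that sustain blood formation over the long term, with 3 libraries of Mmrn1-low and 3 of Mmrn1-high cells. Between 11595104 and 30909990 counts were assigned to genes per library. Libraries of the same group correlated at 0.992 to 0.993 (Pearson's r of log2 CPM across genes, which are not independent replicates), and libraries of different groups at 0.961 to 0.963. The first principal component held 74.8% of the variance and separated the groups. Because the labels do not say that replicates came from separate mice, p-values measure only the spread between these libraries, which may be technical.

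The comparison of Mmrn1-high with Mmrn1-low cells asked how their transcriptomes differ. Lymphoid priming and interferon-stimulated genes rose in Mmrn1-high cells (camera adjusted p = 0.0421 for each with an estimated correlation). Mitotic genes and the list of unfolded protein response and chaperone genes fell (camera adjusted p = 0.0433 for each with an estimated correlation). Plasma cell genes, listed after values had been seen, fell as well (median log2 fold change −0.94). T and natural killer cell markers had a median of 1.65, and B cell markers, which missed the threshold, 0.85. Whether the lymphoid rise lay within the same cells or in the mix of cells was not tested. At the preset correlation, stem cell, megakaryocyte, MHC class II and immediate early genes also rose and granulocyte and monocyte priming genes fell. Those calls were lost with an estimated correlation, in that order at camera adjusted p = 0.0509, 0.0564, 0.0509, 0.110 and 0.0850. That setting also limits the test to the 4 residual degrees of freedom. The correlation of the MHC class II list was estimated at 0.0036, below the preset 0.01, so a higher correlation does not account for its loss. Those of the other lists named were estimated above the preset. The largest fold changes among well-expressed genes were those of Nr4a1, an immediate early nuclear receptor, at 10.6-fold higher in Mmrn1-high cells (log2 fold change 3.41 ± 0.05 SE), and Vcam1, an adhesion receptor, at 14.7-fold higher in Mmrn1-low cells (−3.88 ± 0.05 SE). Vcam1 is also in a tissue macrophage list, written after values had been seen, with a median of −2.89. Whether its difference lay within the same cells or in the mix of cells was not tested. In the edgeR quasi-likelihood test, 9438 of 15419 genes passed the threshold, 4737 higher (50.2%) and 4701 lower (49.8%) in Mmrn1-high cells, with a median absolute log2 fold change of 0.57. Of the 2492 of these with an absolute log2 fold change of at least 1, 1736 were higher and 756 lower. Scaling by library size alone moved log2 fold changes up by a median of 0.15 and gave 6201 higher (66.0%) and 3193 lower (33.99%) genes, so directions here are relative to the TMM scaling. The groups did not overlap for 67.8% of the genes tested, where chance gives 10%.

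Mmrn1 itself (GRCm38 chromosome 6, 60924976 to 60989378) rose from 5.69 ± 0.112 CPM in Mmrn1-low to 10.0 ± 1.33 CPM in Mmrn1-high cells (SD, n = 3), a log2 fold change of 0.82 ± 0.12 SE, with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 4.85e-04. Whether the reporter allele alters the counted transcript was not tested. All 8 surface genes were also higher in Mmrn1-high cells in the edgeR test. Ly6a, which encodes Sca-1, rose from 16.2 ± 1.05 to 61.5 ± 2.16 CPM, and Slamf1, which encodes CD150, from 1.54 ± 0.377 to 4.92 ± 0.403 CPM. Procr rose from 4.34 ± 0.627 to 12.4 ± 1.41 CPM and Itga2b, the platelet integrin CD41, from 63.2 ± 0.921 to 177 ± 1.86 CPM. Cd34 rose from 347 ± 10.4 to 829 ± 16.3 CPM, and Flt3, a cytokine receptor of multipotent and lymphoid progenitors, from 156 ± 1.38 to 546 ± 4.32 CPM. The smallest changes were those of Kit, with a log2 fold change of 0.26 ± 0.03 SE, and Cd48, with 0.51 ± 0.05 SE. Cd48, which gates for LT-HSCs commonly exclude, as they do Flt3, was at 97.7 ± 5.15 CPM in Mmrn1-low and 139 ± 3.35 CPM in Mmrn1-high cells, above Slamf1 in both groups. These transcript levels are not those expected of such a gate, and surface protein was not measured.

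**Figure D1:**
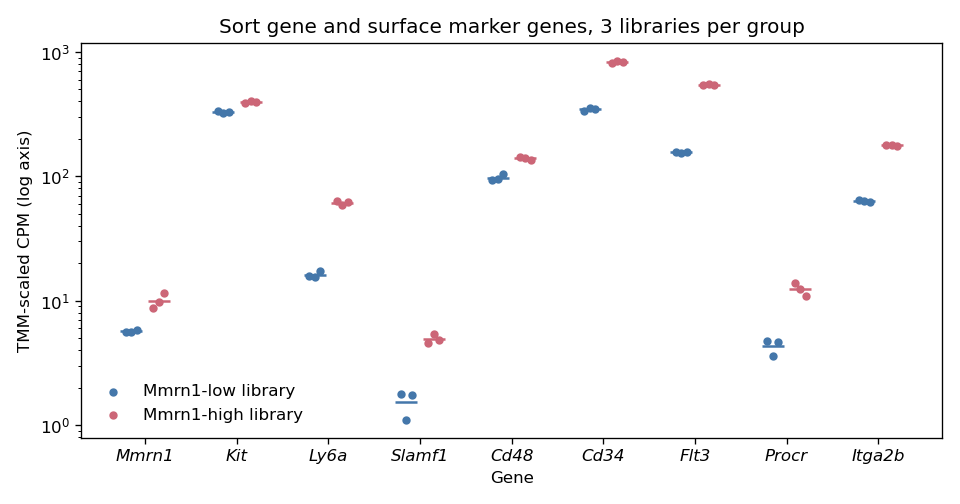
TMM-scaled CPM on a log axis of the sort gene Mmrn1 and 8 surface marker genes. Each point is a library, bars are means of 3 libraries, and every gene is higher in Mmrn1-high (red) than in Mmrn1-low (blue) libraries.

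Of 37 tested members of the stem cell identity list, 32 were higher in Mmrn1-high cells and 1, Lyl1, was lower, with a median log2 fold change of 1.29 (camera, Benjamini-Hochberg adjusted p = 9.67e-10; adjusted p = 0.0509 with an estimated correlation). Among them were Vldlr (1.56 ± 0.04 SE) and the homeobox gene Meis1 (1.68 ± 0.07 SE). Of 28 megakaryocyte and platelet genes, 22 were higher and 2, Fli1 and Rap1b, were lower, with a median of 1.09 (camera adjusted p = 1.94e-05; adjusted p = 0.0564 with an estimated correlation). Examples were F2r, the thrombin receptor (1.79 ± 0.06 SE), and Plek (1.52 ± 0.04 SE). The mature platelet list, a check on adhering platelets that shares 6 of its 11 tested members with other lists, had 8 higher and 2 lower members and a median of 0.96, and missed the threshold (camera adjusted p = 0.0698). Its lower members were Trem3 (−2.28 ± 0.08 SE) and Tmsb4x (−0.54 ± 0.02 SE), and Nrgn (1.60 ± 0.06 SE) and Itgb3 (0.89 ± 0.06 SE) were higher. Trem3 is also in a list of granulocyte progenitors, written after values had been seen, so its fall may not concern platelets. The stem cell ageing list had 19 higher and 6 lower members of 34 and a median of 0.83 (camera adjusted p = 0.0152; adjusted p = 0.127 with an estimated correlation). The call was also lost with library size alone (camera adjusted p = 0.0839), with the filter of 5 CPM (0.238) and with filtered FPKM at a pseudocount of 1 (0.259, with a median of 0.46, and 0.0629 over TMM factors) or 0.1 (0.271). Gem (2.51 ± 0.15 SE) and Fyb (1.02 ± 0.05 SE) were higher. Clu (−3.22 ± 0.08 SE) and the metallothionein gene Mt1 (−1.78 ± 0.05 SE) were lower.

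Of 28 lymphoid priming genes, 27 were higher in Mmrn1-high cells and 0 lower, with a median of 1.45 (camera adjusted p = 4.84e-10; adjusted p = 0.0421 with an estimated correlation). Dntt, the terminal transferase of lymphoid progenitors, rose from 101 ± 3.41 to 544 ± 9.68 CPM, and Gpr171 (1.67 ± 0.05 SE) and Lsp1 (1.54 ± 0.06 SE) rose too. Whether the lymphoid rise lay within the same cells or in the mix of cells was not tested. Of 28 granulocyte and monocyte priming genes, 21 were lower and 3, Csf1r, Lyz2 and Cd33, were higher, with a median of −1.31 (camera adjusted p = 3.41e-07; adjusted p = 0.0850 with an estimated correlation). Mpo, the myeloperoxidase of granules (chromosome 11, 87793581 to 87804413), fell from 12575 ± 434 to 1945 ± 20.6 CPM, and Elane, neutrophil elastase (chromosome 10, 79886247 to 79888215), from 4073 ± 203 to 343 ± 15.9 CPM. Prtn3 (−2.67 ± 0.03 SE), Ms4a3 (−2.83 ± 0.03 SE) and Nkg7 (−2.14 ± 0.03 SE) fell as well. In contrast to these progenitor genes, the list of maturing neutrophils had 15 higher members of 18 and 2 lower, Wfdc21 and Anxa1, and a median of 0.83 (camera adjusted p = 3.85e-05; adjusted p = 0.0509 with an estimated correlation). Its members Retnlg (1.41 ± 0.05 SE), Mmp8 (1.26 ± 0.04 SE), Mmp9 (1.16 ± 0.03 SE) and Lyz2 (1.02 ± 0.03 SE) were higher in Mmrn1-high cells. Erythroid priming genes, 6 higher and 13 lower of 27, had a median of −0.28 (−0.185 to −0.313 with a library left out) and missed the threshold (camera adjusted p = 0.102). Tfrc (−1.14 ± 0.03 SE) and Car1 (−1.15 ± 0.05 SE) were lower.

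Among the markers of other cell types considered next, the T and natural killer cell list alone passed camera at the preset correlation, and the B cell, mononuclear phagocyte, endothelial, mast cell, red cell and stromal lists missed the threshold. T and natural killer cell markers had 11 higher and 0 lower members of 12 and a median of 1.65 (camera adjusted p = 5.24e-04; adjusted p = 0.0509 with an estimated correlation), at low levels except for Lck, which rose from 10.2 ± 0.614 to 37.5 ± 1.51 CPM, beside Gzmb (1.75 ± 0.20 SE) and Klrb1c (1.36 ± 0.17 SE). B cell markers had 9 higher and 1 lower member of 16, with a median of 0.85 (camera adjusted p = 0.0643). The lower member was Igkc, the kappa light chain constant gene, at 542 ± 7.90 CPM in Mmrn1-low and 273 ± 0.382 CPM in Mmrn1-high cells, while Rag1 (1.85 ± 0.22 SE) was higher. Of 19 mononuclear phagocyte markers, 11 were lower and 5, Cd68, Csf1r, Itgax, Siglech and Ms4a6c, were higher, with a median of −0.51 (camera adjusted p = 0.0643). C1qc (−3.59 ± 0.17 SE), Mrc1 (−2.89 ± 0.15 SE), Vcam1 and F13a1 (−0.81 ± 0.03 SE) were lower. Endothelial markers had 7 higher members of 14 and 3 lower, Flt1, Stab1 and Stab2, with a median of 0.31 and a mean of −0.14 (camera adjusted p = 0.286), including Pecam1 (0.86 ± 0.05 SE), Tek (1.18 ± 0.11 SE) and Flt1 (−3.71 ± 0.23 SE). Mast cell and basophil markers had 7 higher of 11 and 2 lower, Hdc and Srgn, and a median of 1.01 (camera adjusted p = 0.102), with Cpa3 at 1.59 ± 0.09 SE and Hdc at −1.41 ± 0.06 SE. Late red cell markers had 2 higher and 4 lower of 12 and a median of −0.10 (camera adjusted p = 0.365). Stromal markers had 3 higher and 3 lower of 7 and a median of −0.09 (camera adjusted p = 0.940). Hbb-bt (0.36 ± 0.05 SE) and Bpgm were higher and Hba-a1, Car1, Fech and Rhd (−0.90 ± 0.13 SE) lower. Among stromal genes Pdgfrb (1.56 ± 0.04 SE), Sparc and Bgn were higher and Cxcl12 (−1.42 ± 0.18 SE), Col1a1 and Col1a2 lower. The red cell and stromal medians turned positive with scaling by library size alone. With a library left out, the endothelial median ranged from −0.0670 to 0.647 and the stromal median from −0.270 to 0.0534.

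All 32 tested mitotic genes were lower in Mmrn1-high cells in the edgeR test, with a median of −1.07 (camera adjusted p = 3.33e-15; adjusted p = 0.0433 with an estimated correlation). Ube2c fell from 234 ± 6.46 to 62.5 ± 0.998 CPM, Cdk1 from 168 ± 4.41 to 71.5 ± 2.29 CPM and Top2a from 1011 ± 8.09 to 575 ± 10.1 CPM. Both groups thus held mitotic transcripts, and the fall does not by itself show quiescence of either group. Lists written after values had been seen, of granulocyte progenitors (median −1.67), plasma cells (−0.94) and tissue macrophages (−2.89), were lower too, and whether the mitotic fall lay within the same cells or in the mix of cells was not tested. DNA replication genes missed the threshold, with 9 higher and 10 lower of 31, a median of 0.01 (0.0042 to 0.0540 with a library left out) and a mean of −0.05 (camera adjusted p = 0.902), and Rrm2 (−0.95 ± 0.03 SE) and Cdc45 (−0.76 ± 0.05 SE) were lower. Of 35 quiescence regulators, 24 were higher and 3, Gfi1, Lrp1 and Hif1a, were lower, with a median of 0.81 (camera adjusted p = 1.98e-05; adjusted p = 0.0509 with an estimated correlation). Egr1 rose from 26.2 ± 1.78 to 209 ± 3.86 CPM and Btg2 from 41.3 ± 2.17 to 99.6 ± 1.47 CPM, and Gfi1 fell (−2.05 ± 0.04 SE). This list shares 18 of its 35 members with other lists, among them the immediate early genes.

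Immediate early genes, which handling of cells induces, had 22 higher and 4 lower members of 26 and a median of 1.499 (camera adjusted p = 4.24e-08; adjusted p = 0.110 with an estimated correlation). Fos rose from 212 ± 7.96 to 933 ± 6.16 CPM, Zfp36 from 237 ± 5.42 to 816 ± 6.76 CPM and Socs3 from 30.5 ± 0.652 to 152 ± 0.889 CPM. The lower members were the heat shock genes Hspa1a, Hspa1b, Hspa8 and Hsp90aa1, of which Hspa1a and Hspa1b are near-identical copies whose reads cannot be told apart with certainty. Interferon-stimulated genes had 28 higher and 0 lower members of 32 and a median of 1.09 (camera adjusted p = 2.77e-08; adjusted p = 0.0421 with an estimated correlation), including Oas2 (1.88 ± 0.08 SE), Ifitm1 (1.12 ± 0.03 SE) and Ddx58, a viral RNA sensor (0.96 ± 0.05 SE). All 10 MHC class II genes were higher in the edgeR test, with a median of 1.58 (camera adjusted p = 5.32e-05; adjusted p = 0.0509 with an estimated correlation). Cd74, the invariant chain, rose from 19.9 ± 2.32 to 61.6 ± 2.75 CPM and H2-Aa from 8.62 ± 0.820 to 35.7 ± 2.38 CPM. The inflammation list had 15 higher and 7 lower of 26 and a median of 0.47 (camera adjusted p = 0.0643), with Ccl3 (2.49 ± 0.08 SE) and Il1r1 (1.61 ± 0.04 SE) higher.

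Of 25 unfolded protein response genes, 20 were lower and 2, Trib3 and Ppp1r15a, were higher, with a median of −1.06 (camera adjusted p = 2.46e-06; adjusted p = 0.0433 with an estimated correlation). Calr, which encodes the chaperone calreticulin, fell from 4236 ± 27.3 to 1510 ± 21.8 CPM, and Sdf2l1 (−2.03 ± 0.04 SE), Hyou1 (−1.53 ± 0.03 SE) and Hsp90b1 (−1.18 ± 0.03 SE) fell. Plasma cells and granulocyte progenitors, which are rich in such chaperones, had markers that moved the same way: 11 of 17 plasma cell genes, listed after values had been seen, were lower and 2 higher, with a median of −0.94. Whether the fall lay within the same cells or in the mix of cells was not tested. Nuclear genes of oxidative phosphorylation had 33 lower and 0 higher members of 41 and a median of −0.31 (camera adjusted p = 1.11e-06; adjusted p = 0.0509 with an estimated correlation), with Cyc1 at −0.77 ± 0.05 SE and Uqcrc1 at −0.74 ± 0.03 SE. Mitochondrially encoded genes, 7 higher and 0 lower of 13, had a median of 0.07 (camera adjusted p = 0.193). With library size alone the median was 0.22 (camera adjusted p = 0.0212), and with FPKM at a pseudocount of 1 also 0.22 (0.00769). The gene mt-Co3 was higher by 0.21 ± 0.03 SE. Glycolytic genes had 14 lower and 6 higher members of 23, a median of −0.51 and a mean of −0.14 (camera adjusted p = 0.0227; adjusted p = 0.197 with an estimated correlation). Eno1 (−1.22 ± 0.04 SE) and Aldoa (−0.98 ± 0.04 SE) fell and the glucose transporter gene Slc2a3 rose (1.24 ± 0.04 SE). Fatty acid oxidation, 5 higher and 8 lower of 23 with a median of 0.06 and a mean of −0.004 (camera adjusted p = 0.902), and autophagy and lysosome genes, 8 higher and 14 lower of 30 with a median of −0.14 (camera adjusted p = 0.258), missed the threshold. The autophagy median was above 0 with library size scaling. The fatty acid oxidation median was −0.0075 without Mmrn1-low replicate 2 and −0.0839 without Mmrn1-high replicate 3. The higher fatty acid oxidation genes included Cpt1a, Acadm, Eci2 and Decr1, and Acaa2 (−0.52 ± 0.04 SE) and Atg12 (−1.02 ± 0.04 SE) were lower. Cytosolic ribosomal protein genes, 17 higher of 44 and 4, Rpl38, Rps2, Rps3 and Rps23, lower, had a median of 0.09 (camera adjusted p = 0.0643), with Rpl22 at 0.54 ± 0.04 SE. The median was 0.24 with library size alone (camera adjusted p = 0.00404) and 0.23 with FPKM at a pseudocount of 1 (7.14e-04).

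TGF-beta and BMP genes had 16 higher in Mmrn1-high cells and 1 lower member, Tgfb1, of 24, with a median of 0.70 (camera adjusted p = 2.06e-04; adjusted p = 0.0509 with an estimated correlation), including Tgfbr2 (0.97 ± 0.05 SE) and the inhibitory Smad7 (1.41 ± 0.10 SE). Notch and Wnt genes had 16 higher and 1 lower member, Jag1, of 23, with a median of 0.88 (camera adjusted p = 4.88e-04; adjusted p = 0.0509 with an estimated correlation), including the Notch target Hes1 (3.39 ± 0.25 SE) and Tcf7 (1.62 ± 0.10 SE). Chromatin regulators had 16 higher and 3 lower members of 31, with Dnmt1, Tet3 and Dot1l lower, and a median of 0.16 (camera adjusted p = 0.0227; adjusted p = 0.178 with an estimated correlation), with Cbx2 (1.61 ± 0.08 SE), Kdm6b (0.87 ± 0.04 SE) and Kmt2a (0.64 ± 0.03 SE) higher. The niche adhesion list, 14 higher and 5 lower of 26 with a median of 0.24 (camera adjusted p = 0.0643), and the p53 and DNA damage list, 14 higher and 4 lower of 28 with a median of 0.10 (0.0843 to 0.194 with a library left out, −0.0045 with FPKM over TMM factors; camera adjusted p = 0.131), missed the threshold. The lower members were Itga5, Vcam1, Spn, Cd81 and Cd63 in the niche list and Bax, Gadd45a, Gadd45b and Fancd2 in the p53 list, and Trp53inp1 (1.43 ± 0.05 SE) and Sesn1 (1.11 ± 0.05 SE) were higher. In camera, 18 of 34 lists passed, 13 of them higher and 5 lower, and the 4 that also passed with an estimated correlation were mitosis, lymphoid priming, unfolded protein response and interferon response. Member counts adjusted over the list alone differed from those over all genes for 6 of the lists: stem cell ageing (20 higher), glycolysis (15 lower), autophagy (9 higher), interferon (29 higher), inflammation (16 higher) and red cell markers (3 lower).

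**Figure D2:**
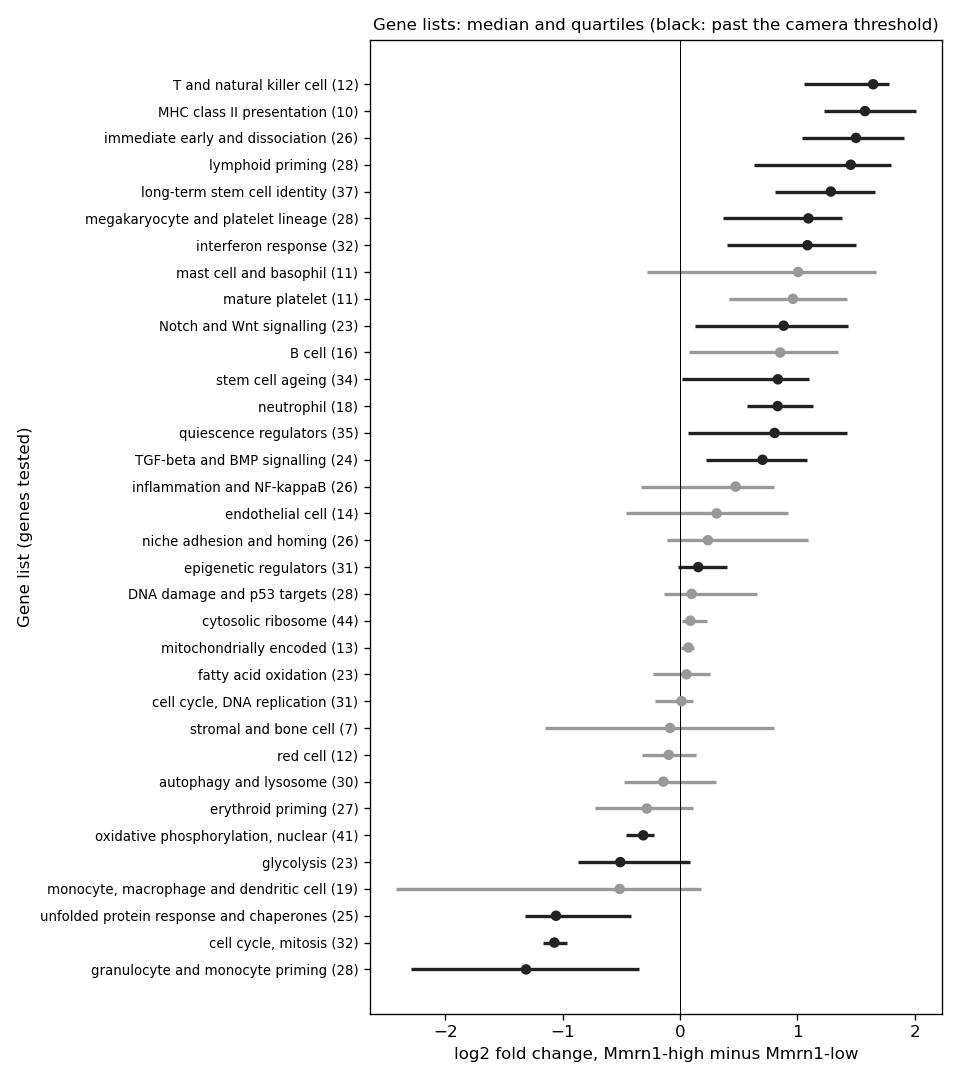
Median log2 fold change (points) and quartiles (bars) of each fixed gene list, Mmrn1-high minus Mmrn1-low, with the number of genes tested in brackets. Lists in black passed the camera threshold at the preset correlation, with T and natural killer cell markers at 1.65 at the top and granulocyte and monocyte priming at −1.31 at the bottom.

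The remaining large fold changes were of varied genes. Higher in Mmrn1-high cells were Rgs1 (3.08 ± 0.10 SE), Ctla2a (2.62 ± 0.07 SE), which has the close paralog Ctla2b, Gimap6 (2.27 ± 0.06 SE), H2-Ob (2.24 ± 0.33 SE), Fosb (2.23 ± 0.05 SE) and Lag3 (2.17 ± 0.08 SE). Lower were Far2 (−3.54 ± 0.11 SE), Prom1, which encodes CD133 (−3.50 ± 0.09 SE), Chst13 (−3.38 ± 0.08 SE), B4galt6 (−3.30 ± 0.05 SE), Dmkn (−3.15 ± 0.11 SE), Cldn15 (−3.09 ± 0.11 SE) and Mgam (−2.98 ± 0.07 SE). Exon bases shared with other annotated genes made up 22.8% of Ube2c, 18.3% of Meis1, 16.3% of Ctla2a, 14.9% of Mpo and 12.6% of Far2.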

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

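All 133 named genes kept their direction under every alternative and left-out library in which they were tested, and the single call lost was that of Fech with unfiltered FPKM values (log2 fold change −0.18). Most of them were chosen for small p or large fold changes in these same libraries, so a kept direction was largely set in advance. The Mmrn1 log2 fold change ranged from 0.41 with FPKM over TMM factors to 0.96 with library size alone, and from 0.71 to 0.90 with a library left out. The count of changed genes stayed within 1.5 times of 9438 except with an absolute log2 fold change of at least 1, which left 2492 by construction. Leaving out a library gave 8601 to 8937 genes, and relative log expression factors called 9414 of the same genes, DESeq2 8088 (7910 genes had no adjusted p) and voom 9323. Genes lower in Mmrn1-high cells numbered 3019, 3011 and 3020 with FPKM at a pseudocount of 1, at 0.1 and without a filter. FPKM divided by TMM factors, at a pseudocount of 1 with the same genes and test, a setting chosen after the data were seen, gave 4455 lower and 3489 higher. With the replicate number as a block, 8923 genes passed. Deviations of same-numbered libraries correlated at 0.04, −0.08 and 0.03, so the numbers were not taken to pair libraries, and the chromatin regulator list missed the threshold with the block (camera adjusted p = 0.0506). With an estimated correlation, which also limits the test to the 4 residual degrees of freedom, 4 lists passed. With fry, which does not compare a list with other genes, 33 passed. Adding 6 lists written after the data were seen left 18 at the preset correlation. Medians that changed sign belonged to lists that missed the threshold. They were DNA replication (−0.0037 with DESeq2) and fatty acid oxidation and p53 (−0.0009 and −0.0045 with FPKM over TMM factors). Autophagy was at 0.0061 with library size alone, 0.0004 with FPKM at a pseudocount of 1 and without a filter, and 0.0047 at 0.1. Red cell markers were at 0.0524 with library size alone. With FPKM they were at 0.0336 (pseudocount of 1), 0.0340 (0.1) and 0.0467 (no filter). Stromal markers were at 0.0629 with library size alone. Library size alone moved log2 fold changes by a median of 0.148, more than the main autophagy (−0.142), red cell (−0.096) and stromal (−0.085) medians. DESeq2 moved them by −0.0158, against a main DNA replication median of 0.0124. The scaling offset is therefore large enough for these signs. FPKM over TMM factors moved them by 0.0025, and the cause of its sign changes was not tested. With a library left out, the fatty acid oxidation, endothelial and stromal medians spanned 0, from −0.0839 to 0.0721, −0.0670 to 0.647 and −0.270 to 0.0534. The ribosomal, mononuclear phagocyte, B cell, niche, erythroid, mitochondrially encoded, p53, inflammation and mast cell lists passed under some alternatives, and the stem cell ageing call was lost with library size alone, the stricter filter and filtered FPKM. At these depths, the simulation recovered 6 of 50 genes at its smallest fold change. It changed 200 genes, whereas 61.2% of the genes tested were called in the data, so its recovery does not measure the sensitivity here.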

Other observations

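All gene lists in this paragraph and the next, and the genes named in them, were chosen after values had been seen, so their counts describe these libraries and are not independent evidence. All 7 called members of the Gimap family, small GTPases of lymphocytes and stem cells, were higher in Mmrn1-high cells, of 8 tested, with a median log2 fold change of 1.81. Of 12 Hoxa and Hoxb genes, 9 were higher and 0 lower, with a median of 0.82, and Hoxa9 rose by 0.81 ± 0.05 SE. Of 15 tissue macrophage genes, 13 were lower and 1, Trf, was higher, with a median of −2.89, and 6 of the 15 are in the fixed lists.

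Of 17 plasma cell genes, 11 were lower and 2, Sdc1 and Trp53inp1, were higher, with a median of −0.94. The immunoglobulin constant genes Igha (382 ± 15.97 CPM in Mmrn1-low, 232 ± 13.5 CPM in Mmrn1-high cells) and Ighg2b (272 ± 0.996 and 98.5 ± 1.26 CPM) were abundant in both groups. Of 13 cytosolic heat shock genes, 12 were lower and 1, Dnajb1, was higher, with a median of −0.48, while the immediate early list rose at the preset correlation (adjusted p = 0.110 with an estimated correlation). Xist, transcribed from the inactive X chromosome, was counted in each of the 6 libraries (368 ± 1.97 CPM in Mmrn1-low, 635 ± 10.7 CPM in Mmrn1-high cells). So were the Y-linked genes Ddx3y (19.3 ± 2.85 and 19.9 ± 2.38 CPM) and Eif2s3y (20.7 ± 0.760 and 14.99 ± 0.909 CPM). Each library therefore likely held RNA of female and male cells, and so of more than a single mouse. Xist was higher, Eif2s3y lower and Ddx3y similar in Mmrn1-high libraries, and whether the mix of sexes differed between the groups was not tested.

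Of the tests below, those of counting noise and of exon overlap were set before their results were seen, and the others after. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 9438 genes and the highest other gave 2, but 10 splits are too few for a share under 0.05.

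Transcripts of 144 immunoglobulin V genes, which mark B lineage clones, separated the groups: 17 were higher and 104 lower in Mmrn1-high cells, with log2 fold changes from −8.62 to 3.10. Levels correlated at 0.971 to 0.983 within groups and 0.590 to 0.617 between them (across genes), and 6 genes, such as Igkv1-132 at 38, 32 and 74 counts, were in every Mmrn1-low and in no Mmrn1-high library. A shared shift in germline transcription is argued against by the SD of their fold changes, 2.385 times that of genes matched on counts. Replicates of a group drawn from a single pool of cells may account for it: the median within-group chi-square per V gene was 0.796 times that of matched genes, where separate animals would bring their own clones. With a single pool per group, p-values would measure technical spread, and a difference between the Mmrn1 states themselves stays open.

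Granulocyte priming genes were lower in Mmrn1-high cells (a call lost with an estimated correlation, camera adjusted p = 0.0850) although both groups were labelled LT-HSCs, and Mpo alone took 1.15% to 1.23% of the counts of Mmrn1-low libraries. With library sizes taken without the 10 most abundant genes the list's median was −1.18. These genes held 4.0% to 5.1% of the counts of a library, so leaving them out could hardly move the median, and the outcome was largely fixed in advance. It is this small share that argues against these genes setting the scaling. An excess of maturing neutrophils in the Mmrn1-low over the Mmrn1-high libraries is argued against by the neutrophil list's median of 0.83. This does not show that such cells were absent. The list's member Ngp, which is not separate evidence, was at 597 ± 29.7 CPM in Mmrn1-low and 1182 ± 5.62 CPM in Mmrn1-high cells. Both groups thus held neutrophil transcripts. A larger share of granulocyte-committed progenitors in the Mmrn1-low gate could not be told apart from a change within stem cells: a further list of 20 progenitor genes had a median of −1.67, but most of its members had been seen as lower before it was written, so that test decides nothing. A difference tied to the Mmrn1 state stays open.

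Single abundant genes sat at different levels in replicate libraries: for 112 of 6752 genes with a mean log2 CPM of at least 5, a library lay over 1 log2 unit from the other 2 of its group, which agreed within 0.25. Rab43, of whose exon bases 75.35% are shared with other genes, was at 83.5 and 79.5 CPM in Mmrn1-low replicates 1 and 2 and 8.29 in replicate 3, and at 101 and 98.9 CPM in Mmrn1-high replicates 1 and 3 and 10.3 in replicate 2. The library apart had the largest count total of its group in both groups for Rab43 and the smallest in both for Nfe2. For Cipc it had the smallest total in Mmrn1-low alone. Among other genes with a library apart in both groups, Mob1a and Lrrc8d were like Rab43, Ncoa4 and Zfp740 like Nfe2, and Aak1 and Tmem170b like Cipc. From the smallest to the largest count total, the libraries held 26, 18 and 25 cases in Mmrn1-low. In Mmrn1-high they held 29, 21 and 22. The library with the middle total thus held the fewest cases in each group. Whether the pattern follows sequencing depth was not tested. Counting noise is argued against, since counts drawn from the fitted dispersion trend gave 0 such genes, and so is RNA of another cell type in a single library, since the most affected library held 20.6% of the cases. Exon overlap was 1.30 times as common among the 112 genes as among matched genes, which the rule set beforehand counted against reads shared with an overlapping gene. The 95% bootstrap interval, added after that value was seen, was 1.03 to 1.60 and reached past that rule's limit. This explanation was therefore left open for the 51 genes with exon overlap, while 61 genes had none. Beyond RNA of another cell type, no biological explanation was tested, and 1 of the 112 genes, Tfec, passed the edgeR test between groups.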
